A study of Homo sapiens with 6 samples.

How the data were processed

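The data are 6 single-colour Affymetrix whole-transcript arrays of HCT116 cells, 3 labelled control (an siRNA against GFP) and 3 labelled siChe-1, taken 48 h after transfection. The values are log2 intensities that the authors made with RMA in Affymetrix Expression Console, per the submitters' processing notes, which give no version. RMA corrects the background, applies quantile normalization between arrays and summarises the probes of a probe set by median polish. That RMA was run with its usual settings is not given in the sources used here. The deposited log2 values of all 6 arrays had medians between 4.95 and 5.05 and were not centred by gene. Quantile normalization makes the overall distributions alike, so a change in total RNA per cell cannot be seen, and RMA compresses the differences of dim genes. The table holds no detection calls, so a value near the low end may be background. The scanner files were not used here, so the background correction could not be varied.

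The table has 33297 probe sets. The platform annotation paired 19460 with 1 gene symbol and 1754 with several, and 12083 were not listed. A gene was named only from probe sets with 1 symbol. The gene identifiers of 19429 of these were found in the NCBI table of genes (assembly GRCh38.p14), which changed the symbol of 0. For the 769 genes with more than 1 probe set, the one with the highest mean over the 6 arrays was used, leaving 18417 genes. No coordinates are given because the build of the array design is not named. There were 0 columns of values other than those of the 6 samples.

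Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, no filter on dim genes) as arrays labelled siChe-1 minus arrays labelled control. Benjamini-Hochberg adjusted p-values under 0.05 over all 18417 genes were called changed. Errors of a group are SDs over 3 arrays and errors of a difference are moderated SEs. Gene lists were written from textbook knowledge before the data were examined, with 26 lists of which 25 had at least 5 measured members. The list of mitochondrially encoded transcripts had no named probe set, and AATF was left out of list counts. List members without a named probe set were not analysed here. Lists were tested with camera (two-sided, inter-gene correlation 0.01, Benjamini-Hochberg over the 25 lists). This asks whether a list moved apart from the other genes, and it was repeated with a correlation estimated from the data. Fry, which asks whether the members moved one way on balance without comparing them with other genes, was an alternative. By camera 13 lists passed, by fry 12, and with an estimated correlation 1, the interferon-stimulated genes. Counts of list members use the adjusted p over all genes unless they are said to be adjusted over the list alone. Some genes are in more than one list.

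The genes named were fixed by a rule written before the data were examined. They were AATF, the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap, and up to 4 called members per list with the largest change (all of them where 5 or fewer passed, and the 2 with the smallest p where none did). This gave 81 genes. IFITM2, PSMB8, PTPRC, COL3A1, TYROBP and TAGLN were named outside this rule, and the text says which others were named after their values were seen.

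Before use, the test was tested on simulated data for this comparison, in which 18417 genes were drawn from the means and SDs of the real genes and 200 were changed. It recovered 78% of 2-fold changes and 100% of 4-fold changes. False calls made up 2.67% of calls. Camera called a list of 30 genes shifted by 0.5 and did not call an unchanged list. The simulated genes varied independently, while the correlation estimated in the real data was 0.33 for the assembly factors and 0.56 for the checkpoint list. The simulation therefore does not check the camera p-values of correlated lists.

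The alternatives were another quantile normalization, centring on array medians, leaving out the dimmest 40% of genes, testing all rows, averaging the probe sets of a gene, an intensity trend with a robust prior, array weights, the replicate number as a block, stricter thresholds, the other set tests and leaving out each array in turn. The labels number the replicates 1 to 3 in both groups without saying that a number marks a shared culture or day, so the main fit has no block. The labels give no scan date or batch.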

Results

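Gene expression was measured in HCT116 cells, an established human colorectal carcinoma line, 48 h after transient transfection with one of 2 kinds of siRNA. The control duplex was directed against GFP, which these cells do not make, and the other duplex was directed against Che-1, the protein encoded by AATF, a nucleolar and transcription-associated factor. There were 3 arrays labelled control and 3 labelled siChe-1, each a biotin-labelled whole-transcript Affymetrix array made from 6 micrograms of total RNA. The comparison asks which transcripts differ when Che-1 is depleted. The median RMA intensity of an array, over all 33297 probe sets, lay between 4.95 and 5.05 on the log2 scale, and 18417 named genes were tested. Nothing in the labels says whether the 3 arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, and the number of arrays limits the precision.

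The targeted gene went against the labels. AATF was higher in the arrays labelled siChe-1 than in those labelled control, at 8.74 ± 0.18 against 7.62 ± 0.12 (log2 RMA intensity, SD, n = 3 each). The difference was 1.12 ± 0.13 on the log2 scale (SE), which is 2.17-fold, with a 95% confidence interval of 0.82 to 1.41 and limma adjusted p = 0.00122. The 3 arrays labelled control read 7.55, 7.75 and 7.55 and the 3 labelled siChe-1 read 8.53, 8.81 and 8.87, so the groups did not overlap. AATF in the arrays labelled control was 46.1% of its level in the arrays labelled siChe-1. An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest p that 3 arrays against 3 allow. Because the depleted gene was not lower where the label says it was depleted, groups are named below by their labels. "Higher" and "lower" mean in the arrays labelled siChe-1 relative to those labelled control. Every direction would turn if the labels of the groups were exchanged.

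**Figure D1:**
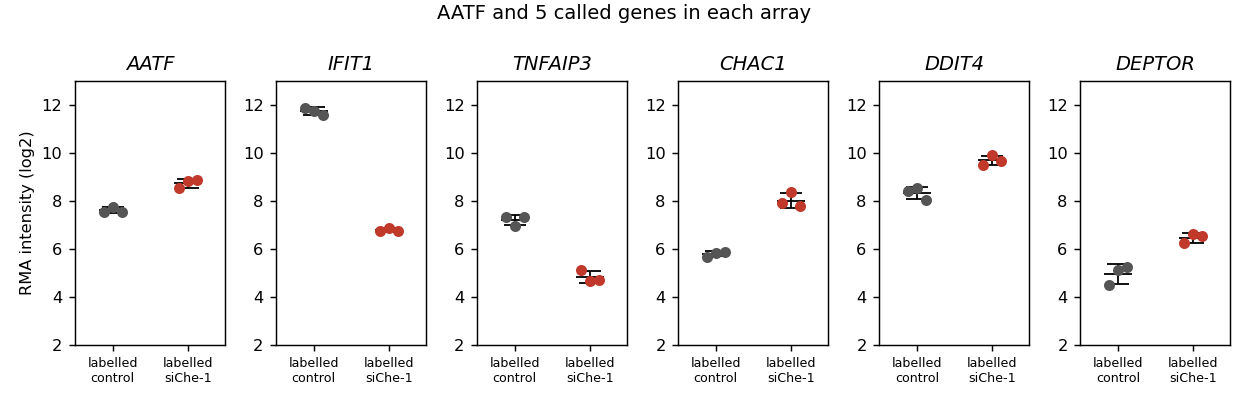
RMA intensity (log2) of AATF and of 5 genes that passed the test, in each of the 6 arrays. Points are arrays, and the bars give the mean and SD of 3 arrays per labelled group. AATF was 8.74 in the arrays labelled siChe-1 and 7.62 in those labelled control.

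Of the 18417 genes, 685 differed at an adjusted p under 0.05 by limma, 220 of them higher and 465 lower, and all 685 had groups that did not overlap. Over all genes, 24.0% had groups that did not overlap, where chance gives 10%. The lower genes went much further: 48 were lower by at least 4-fold and 1 was higher by at least 4-fold. The gene higher by at least 4-fold was CHAC1, which degrades glutathione, at 4.64-fold (8.01 ± 0.31 against 5.80 ± 0.11, SD, n = 3 each, limma adjusted p = 2.97e-05). The other 9 of the 10 largest rises were GPR15 (log2 difference 1.80), SESN3 (1.75), SLC7A11 (1.63), KLRC4-KLRK1 (1.56), DEPTOR (1.51), DDIT4 (1.36), H2BC7 (1.36), SESTD1 (1.34) and MAN1A1 (1.31), with adjusted p between 0.000897 for GPR15 and 0.0246 for KLRC4-KLRK1. KLRC4-KLRK1 is a read-through transcript that overlaps other genes, and H2BC7 has near-identical histone copies, so the identity of these signals is uncertain. KLRC4-KLRK1 also read 3.95 in the arrays labelled control, a level not shown to be above background, so the size and rank of its rise are uncertain. The same holds for GPR15, which read 4.48 there, near the fibroblast marker TAGLN (4.35). SESN3 read 4.73 there, also not shown to be above background, so the size of its rise is uncertain too. Without siChe-1 replicate 1 the count was 1565 (739 higher and 826 lower). It was 273, 290 and 272 without control replicate 1, 2 or 3, 462 without siChe-1 replicate 2, and 350 without siChe-1 replicate 3.

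Interferon-stimulated genes were far lower in the arrays labelled siChe-1, that is, far higher in the arrays labelled control. Of 31 measured members, 29 were lower, none was higher and 2 did not pass, and the median difference was -2.96 on the log2 scale, or 7.78-fold. IFI44 showed the largest measured difference, at 8.69 ± 0.11 in the arrays labelled control and 3.14 ± 0.16 in those labelled siChe-1 (SD, n = 3 each), a 46.7-fold difference with limma adjusted p = 1.66e-08. Its level in the arrays labelled siChe-1 was near that of leukocyte markers there (list median 3.31) and is not shown to be above background. The same holds there for IFI44L (3.15), IFIT3 (4.15) and IFIT2 (4.24), which lie in the range of markers of other cell types such as COL3A1 (4.24), so the measured folds and the order of these genes are uncertain. IFIT2 was lower by a measured 41.0-fold, IFI6 was 32.7-fold lower and IFIT1 was 31.2-fold lower. IFIT1 and IFIT2 encode proteins that bind foreign RNA. IFIT1 stood at 11.7 ± 0.16 in the arrays labelled control, among the brighter probe sets, against 6.78 ± 0.07. The remaining 6 of the 10 largest falls were SAMD9 (log2 difference -4.75), OAS1 (-4.74), OASL (-4.68), IFIT3 (-4.67), IFI44L (-4.59) and IFITM1 (-4.45). SAMD9 (4.78), OAS1 (4.72) and OASL (4.82) also read low in the arrays labelled siChe-1. These levels are not shown to be above background, so the sizes of these falls are uncertain too. OAS1 makes the 2-5A messenger that activates RNase L. The members that did not pass were IFITM2 (-0.54, adjusted p = 0.103) and PSMB8 (-0.37, adjusted p = 0.226). PSMB8 read 3.88 in the arrays labelled control and 3.51 in those labelled siChe-1. These levels are not shown to be above background, so they do not show that PSMB8 was unchanged.

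Of the 48 genes lower by at least 4-fold, 21 were in the interferon list. The list stood apart from the other genes by camera (adjusted p = 2.08e-75 over 25 lists), and it kept adjusted p = 0.00338 with an estimated correlation between genes. All 31 members were lower when p was adjusted over the list alone. Between 28 and 30 members were lower when any 1 array was left out. Of 15 leukocyte markers, CD68 was also lower in the arrays labelled siChe-1 (8.23 ± 0.21 to 6.68 ± 0.28, SD, n = 3 each, limma adjusted p = 0.000553), and the other 14 did not pass. PTPRC read 2.41 ± 0.12 in the arrays labelled control and 2.46 ± 0.16 in those labelled siChe-1, both near the low end of the scale.

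**Figure D2:**
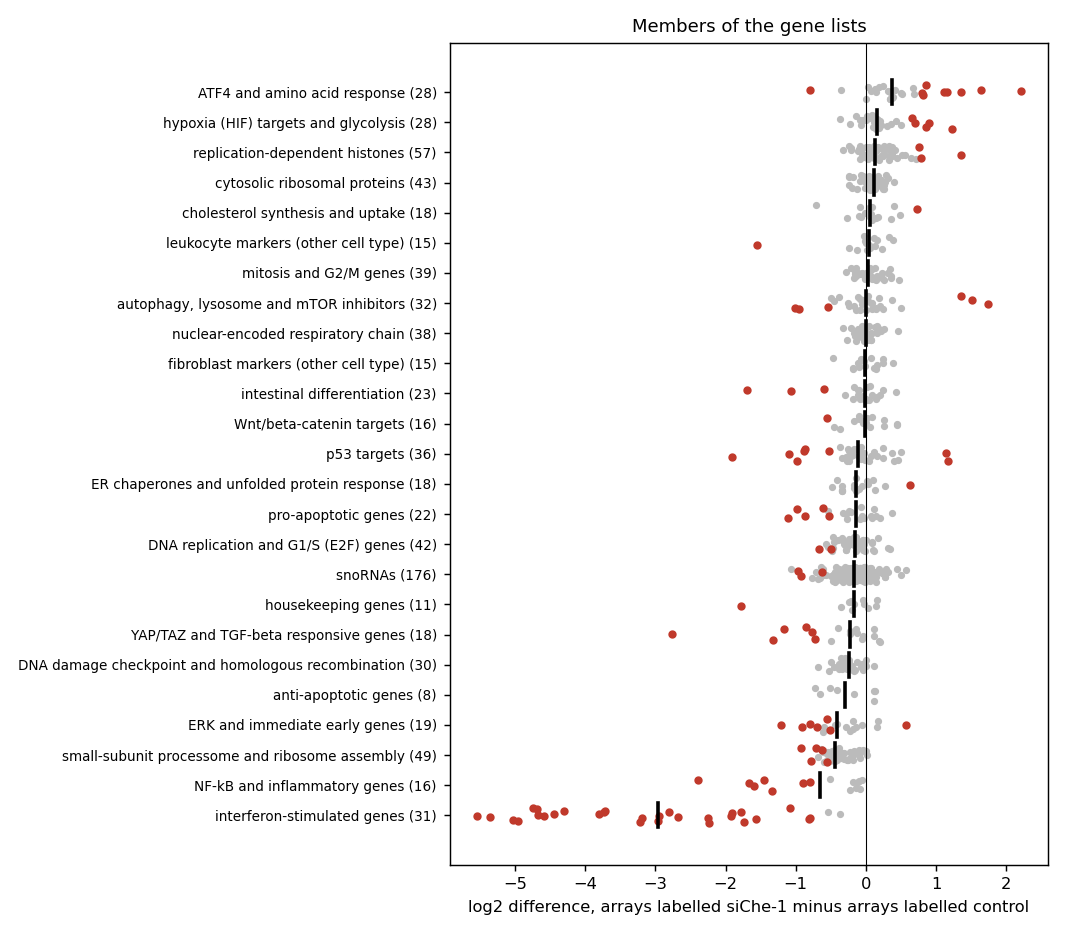
Log2 difference (arrays labelled siChe-1 minus arrays labelled control) of each measured member of 25 gene lists, with the number of members in brackets. Points are genes, red where the limma adjusted p is under 0.05 and grey otherwise, and black bars are list medians. The interferon-stimulated genes have a median of -2.96, the lowest of the 25, and the ATF4 list has the highest, 0.38.

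Inflammatory, immediate early and matrix-responsive genes were also lower in part. In the NF-kB list, 7 of 16 members were lower, none was higher and 9 did not pass (median -0.65, adjusted p = 0.136 with an estimated correlation). TNFAIP3, which encodes the NF-kB inhibitor A20, was lower by a measured 5.23-fold (7.21 ± 0.21 to 4.82 ± 0.25, SD, n = 3 each, limma adjusted p = 1.70e-05). Its level of 4.82 is not shown to be above background. CXCL8, a neutrophil chemokine, was 3.16-fold lower, RELB was 3.01-fold lower and NFKBIA was 2.72-fold lower. Of 19 genes of the ERK and immediate early list, 6 were lower and 1 was higher (median -0.41, adjusted p = 0.136 with an estimated correlation). FOSL1 was 2.31-fold lower, and JUN (-0.92), ATF3 (-0.80) and SPRY2 (-0.70) followed, all given as log2 differences. SPRY2 read 4.34 in the arrays labelled siChe-1, a level not shown to be above background. The single higher member was DUSP6, an ERK phosphatase, at 0.57, named after its value was seen. Of 18 genes responsive to YAP/TAZ or TGF-beta, 6 were lower and 12 did not pass (median -0.22, adjusted p = 0.169 with an estimated correlation). SNAI2, a repressor of epithelial genes, was lower by a measured 6.79-fold, to 3.73, a level not shown to be above background. CCN1 was 2.51-fold lower, THBS1 was 2.24-fold lower and AXL was 1.81-fold lower.

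With p adjusted over the list alone, 9 NF-kB genes, 9 ERK genes and 8 YAP/TAZ genes were lower, and 1 ERK gene was higher. By camera the adjusted p was 1.90e-10 for NF-kB, 1.64e-05 for ERK and 3.50e-05 for YAP/TAZ. At the preset correlation the 9 other ways of splitting the 6 arrays 3 against 3 gave between 5 and 11 lists past the threshold, against 13 for the labelled groups. Without siChe-1 replicate 1, 9 NF-kB genes and 10 ERK genes were lower, and without any other single array DUSP6 did not pass. Without siChe-1 replicate 3, or without control replicate 1 or 3, 3 ERK genes were lower, and without siChe-1 replicate 3 or control replicate 3, 3 YAP/TAZ genes were lower.

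Some genes of the amino acid response were higher. In the ATF4 list, 8 of 28 members were higher, 1 was lower and 19 did not pass (median 0.38, adjusted p = 0.179 with an estimated correlation). Beside CHAC1, SLC7A11, the cystine transporter, was 3.11-fold higher (8.91 ± 0.75 against 7.27 ± 0.12, SD, n = 3 each, limma adjusted p = 0.0150), DDIT4 was 2.57-fold higher, and ASNS, asparagine synthetase, was 2.24-fold higher. ATF3 was the lower member. DDIT4 and DEPTOR, inhibitors of the mTOR kinase, and SESN3, a sestrin, were the 3 higher members of the list of autophagy, lysosome and mTOR inhibitor genes. In that list CTSL, a lysosomal protease, was 2.02-fold lower, and the other 2 lower members, named after their values were seen, were ATG12 (-0.95) and LAMP1 (-0.53). The other 26 of its 32 members did not pass, its median was 0.0031, and it was not shifted by camera (adjusted p = 0.934). DEPTOR read 6.47 ± 0.21 against 4.95 ± 0.42, and DDIT4 9.69 ± 0.20 against 8.33 ± 0.26 (SD, n = 3 each). Of 28 HIF targets and glycolytic genes, 5 were higher and 23 did not pass (median 0.15, adjusted p = 0.169 with an estimated correlation). ALDOC, an aldolase, was 2.33-fold higher, NDRG1 was 1.87-fold higher, EGLN3, an oxygen-sensing prolyl hydroxylase, was 1.80-fold higher, BNIP3L was 1.62-fold higher and ENO2 was 1.57-fold higher.

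In the counts adjusted over the list alone, 14 ATF4 genes were higher and 1 lower, 7 HIF genes were higher, and 4 autophagy genes were higher and 4 lower. Camera gave adjusted p = 3.74e-10 for the ATF4 list and 0.000205 for the HIF list. Without siChe-1 replicate 1, in which SLC7A11 (8.05) and SESN3 (5.66) were the lowest of their group, 15 ATF4 genes were higher. Without control replicate 1 or 3, 2 HIF genes were higher.

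A few nucleolar assembly factors were lower, against the direction of AATF, which is itself a member of the small-subunit processome and was left out of this list. Of 49 measured factors, 5 were lower, none was higher and 44 did not pass (median -0.44, adjusted p = 0.179 with an estimated correlation). Of the 49, 47 had a difference below 0. NOL6 was 1.90-fold lower (6.88 ± 0.21 against 7.80 ± 0.10, SD, n = 3 each, limma adjusted p = 0.00464). RRS1 was 1.72-fold lower, NOP2 was 1.64-fold lower, RRP9 was 1.54-fold lower and PES1 was 1.47-fold lower. Of 176 snoRNAs, 3 were lower (SNORD14E, SNORD51 and SNORA62, by 0.96, 0.93 and 0.62 on the log2 scale, SNORD51 to 3.64, not shown to be above background), and 173 did not pass (median -0.16, adjusted p = 0.169 with an estimated correlation). No ribosomal protein gene of 43 passed (median 0.11, adjusted p = 0.615 with an estimated correlation), the nearest being RPL3 (0.29, adjusted p = 0.230) and RPL7A (0.40, adjusted p = 0.245). Many snoRNAs lie in introns of host genes, so their signal can include host gene transcripts. Ribosomal protein genes have many processed copies, so their signal can be shared between copies.

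The counts adjusted over the list alone were 25 assembly factors and 2 snoRNAs lower, and no ribosomal protein gene passed by limma, with 2 at an unadjusted p under 0.05. Camera gave adjusted p = 7.88e-15 for the assembly factors, 3.50e-05 for the snoRNAs and 0.0491 for the ribosomal proteins. Without siChe-1 replicate 1 the median of the assembly factors was -0.28, 9 assembly factors and 9 snoRNAs were lower and 1 snoRNA was higher. Without any single control array, 2 assembly factors were lower, 3 were without siChe-1 replicate 3, and 1 snoRNA was lower without control replicate 1 or 2. The ribosomal protein call was lost without siChe-1 replicate 1 (adjusted p = 0.174), siChe-1 replicate 3 (0.124) or control replicate 3 (0.507, with a median of 0.060).

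Few cell cycle genes passed. No mitotic gene of 39 passed (median 0.027, adjusted p = 0.830 with an estimated correlation), with PIMREG at 0.36 (adjusted p = 0.127) and NUF2 at 0.47 (adjusted p = 0.144). Of 42 replication and E2F genes, 2 were lower, GINS3 (1.59-fold) and POLA2, a subunit of DNA polymerase alpha (1.41-fold), and 40 did not pass (median -0.16, adjusted p = 0.169 with an estimated correlation). No checkpoint or recombination gene of 30 passed (median -0.24, adjusted p = 0.515 with an estimated correlation), the nearest being CHEK2 (-0.68, adjusted p = 0.0695) and PALB2 (-0.46, adjusted p = 0.0769). Of 57 replication-dependent histone genes, 3 were higher (H2BC7 by 2.56-fold, H2AC13 by 1.73-fold and H4C4 by 1.70-fold) and 54 did not pass (median 0.13, adjusted p = 0.169 with an estimated correlation). As adjusted over the list alone, 9 replication genes were lower, 5 histone genes were higher, and no mitotic or checkpoint gene passed by limma, with 6 and 7 at an unadjusted p under 0.05. Camera gave adjusted p = 0.000212 for the replication list, 0.000255 for the checkpoint list, 0.000249 for the histones and 0.248 for mitosis. Without siChe-1 replicate 1, 5 mitotic genes were higher and that list passed camera (adjusted p = 0.000867), but not with an estimated correlation (adjusted p = 0.263). In that setting the checkpoint list did not pass camera (median -0.095, adjusted p = 0.355), and 5 replication genes were lower and 5 histone genes higher. Without any single control array no replication gene passed, nor without siChe-1 replicate 3, and 1 was lower without siChe-1 replicate 2, as was 1 checkpoint gene. The histone count fell to 0 without control replicate 1, and to 1 without control replicate 2 or 3 or siChe-1 replicate 3.

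The p53 targets moved in both directions. Of 36 measured, 6 were lower, 2 were higher and 28 did not pass (median -0.12, camera adjusted p = 0.114, and adjusted p = 0.497 with an estimated correlation). PLK2, a polo-like kinase, was 3.76-fold lower (6.67 ± 0.23 against 8.58 ± 0.10, SD, n = 3 each, limma adjusted p = 3.44e-05), and AEN, an apoptosis-enhancing nuclease, was 2.13-fold lower. TP53INP1 was 2.25-fold higher and GDF15, a stress-induced cytokine, was 2.20-fold higher. Of 22 pro-apoptotic genes, 5 were lower and 17 did not pass (median -0.15, adjusted p = 0.136 with an estimated correlation). These were the death receptors TNFRSF10A (2.16-fold) and FAS (1.83-fold), PMAIP1, which encodes the BH3-only protein NOXA (1.97-fold), CASP8 (1.53-fold) and BAK1 (1.44-fold). None of 8 anti-apoptotic genes passed by limma (median -0.29, 3 at an unadjusted p under 0.05), with BCL2L1 at -0.72 (adjusted p = 0.0689) and CFLAR at -0.52 (adjusted p = 0.0843).

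Among members adjusted over the list alone, 6 p53 targets were lower and 6 higher, 6 pro-apoptotic genes were lower and 2 anti-apoptotic genes were lower. Camera gave adjusted p = 0.00190 for the pro-apoptotic and 0.116 for the anti-apoptotic list, the latter with adjusted p = 0.282 with an estimated correlation. Without control replicate 1 or 3, 1 pro-apoptotic gene was lower, 2 were without control replicate 2 and 3 without siChe-1 replicate 3. Without control replicate 1, 3 p53 targets were lower, and without siChe-1 replicate 1, 4 were higher. The p53 list passed camera without control replicate 2 (adjusted p = 0.0439), but not with an estimated correlation (adjusted p = 0.295).

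In the remaining lists few genes passed. Among 23 genes of intestinal differentiation, KLF4 was 3.23-fold lower, CEACAM1 a measured 2.09-fold lower (to 3.96, not shown to be above background) and KRT19 1.51-fold lower, and 20 did not pass. Of 16 Wnt/beta-catenin targets MYC alone passed (1.47-fold lower). Of 18 ER chaperones and unfolded protein response genes HERPUD1 passed (1.55-fold higher), and of 18 cholesterol genes TM7SF2 passed (1.65-fold higher). None of 38 respiratory chain genes passed by limma (1 at an unadjusted p under 0.05), with UQCRC2 at 0.46 (adjusted p = 0.119) and NDUFS4 at -0.33 (adjusted p = 0.315). Of 11 housekeeping genes B2M alone passed, at 3.44-fold lower (8.81 ± 0.21 against 10.6 ± 0.13, SD, n = 3 each, limma adjusted p = 5.72e-05). B2M is the light chain of MHC class I.

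Of the markers of other cell types, no fibroblast marker of 15 passed by limma (2 at an unadjusted p under 0.05), with ACTA2 at -0.46 (adjusted p = 0.0834) and COL1A1 at 0.38 (adjusted p = 0.107). Of 15 leukocyte markers CD68 alone passed, at 2.94-fold lower, from 8.23 ± 0.21 (SD, n = 3), above the other leukocyte markers, whose list had a median of 3.32 in the arrays labelled control. Camera did not pass for any of these 8 lists (adjusted p = 0.264 for intestinal differentiation, 0.842 for Wnt, 0.110 for ER chaperones, 0.139 for cholesterol, 0.934 for the respiratory chain, 0.0766 for housekeeping, 0.831 for fibroblast and 0.664 for leukocyte markers). The median and the mean differed in sign for the fibroblast (-0.011 and 0.014), leukocyte (0.047 and -0.033) and respiratory chain (-0.0051 and 0.0039) lists, all of them close to 0. Counts adjusted over the list alone were these: 3 intestinal genes were lower, 3 Wnt targets were lower and 2 higher, 2 ER chaperone genes were lower and 1 higher, 1 cholesterol gene was lower and 4 higher, and 1 housekeeping and 1 leukocyte gene were lower. The ER chaperone, Wnt and intestinal counts depended on single arrays: the HERPUD1 call was lost without control replicate 2 or 3 or siChe-1 replicate 2 or 3, the MYC call was lost without any array but siChe-1 replicate 1, and 1 intestinal gene was lower without siChe-1 replicate 2 or control replicate 2 or 3. Without siChe-1 replicate 1, 2 ER chaperone, 2 Wnt, 2 housekeeping, 1 cholesterol and 1 fibroblast gene were lower and 1 respiratory chain gene was higher. Without siChe-1 replicate 3 the housekeeping list passed camera (adjusted p = 0.0408), but not with an estimated correlation (adjusted p = 0.241).

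One array stood apart from the others. The first principal component of the named genes, with 50.5% of the variance, separated the labelled groups, and the second, with 26.8%, separated siChe-1 replicate 1 (score 26.8) from siChe-1 replicates 2 (-22.1) and 3 (-17.5). Across genes, siChe-1 replicate 1 differed from replicates 2 and 3 with an SD of 0.39 and 0.37 on the log2 scale, while these replicates differed from each other with an SD of 0.20 and the control arrays with SDs of 0.23 to 0.25. No pair of arrays held identical data: between 21 and 73 of the 33297 values were equal in any pair, to every digit given and with no tolerance.

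**Figure D3:**
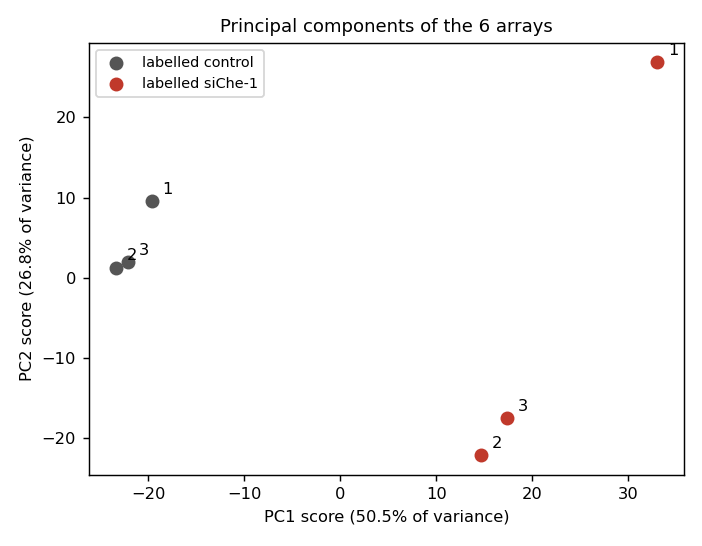
Scores of the 6 arrays on the first and second principal components of 18417 named genes (log2 RMA intensity), with 50.5% and 26.8% of the variance. Points are arrays, numbered by replicate. The labelled groups separate along the first component and siChe-1 replicate 1 lies apart from its group along the second.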

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

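The rank of AATF, the tests of a single swap, of the nucleolar factors, of mixing into siChe-1 replicate 1 and of gene length as the whole of its difference, and the count of probe sets outside the named genes, were chosen only after the result was seen.

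Probe sets outside the named genes also differed. In the fit of all rows, 21 of 12083 probe sets with no listed gene and 6 of 1754 with several symbols were higher in the arrays labelled siChe-1 than in those labelled control, while 44 and 29 were lower. The log2 differences of these calls ran from -4.23 to 1.35 for probe sets with no listed gene and from -3.51 to 1.95 for those with several symbols.

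AATF was higher where the label says that it was depleted. A swap of a single array between the groups is argued against, since 0 arrays lay on the other group's side in AATF or in the median of the interferon list. AATF did not move with the list of small-subunit processome and ribosome assembly genes, which is not limited to factors that AATF works with. The list had a median of -0.438 (-0.28 without siChe-1 replicate 1) and AATF rose by 1.12. Of its 49 measured members 44 did not pass, and camera gave adjusted p = 0.179 with an estimated correlation. An exchange of the 2 groups' labels stays open: 0.119% of the 18417 genes rose by as much as AATF, but this restates the observation that raised the question and is no test of it. It also stays open that AATF may itself respond to the siRNA or to the interferon state of the arrays labelled control, which cannot be separated from the groups in this design. The siRNA sequences and a protein measurement were not used here.

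Interferon-stimulated genes were higher in all 3 arrays labelled control. RNA of leukocytes is argued against, since the leukocyte markers had a median log2 difference of 0.0469 and PTPRC was near the low end of the scale in both groups (2.41 in the arrays labelled control and 2.46 in those labelled siChe-1). CD68, the one marker of 15 that passed the test, was higher in the arrays labelled control and stood above the other leukocyte markers in both groups, the next being TYROBP at 5.84 and 6.07. Array brightness or scaling was not decided by rescaling. The 2 other scalings moved the median of the list by at most 1.3%, but RMA had already made the arrays alike, so a large move was not possible. What the deposited values show is narrower: array medians lay between 4.95 and 5.05, a small range beside the list median of -2.96. A response to one of the siRNA duplexes remains a candidate explanation, and the design cannot say whether it would be the control or the siChe-1 duplex while the labels are in doubt.

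Array siChe-1 replicate 1 differed from replicates 2 and 3 of its group. Mixing with RNA of the other group is argued against, since its interferon genes differed from the mean of the other 2 arrays by a median of -0.0846, where mixing would raise them. Its difference fell with gene span (Spearman rho -0.29 across 18389 genes, which are not independent replicates), while replicate 2 minus replicate 3 gave 0.12 and pairs of control arrays between -0.088 and -0.027. A trend with gene length may therefore be part of the difference, as RNA or labelling quality could give. After the trend was removed 89.9% of the variance was left, so length is not the whole of it. What was left includes array noise, which no trend could remove. The difference of this array from the other 2 of its group had an SD of 0.37, and that of the other arrays had SDs of 0.20 to 0.25. GC content was not tested, and no biological explanation was tested because the design names none for a single replicate.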

How the results depend on the processing

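AATF kept its direction and limma call under all of the alternatives, with log2 differences of 1.05 to 1.23 and adjusted p of 4.33e-06 to 0.0154, and only the exact permutation test (1.12, p = 0.1) cannot pass with 3 arrays against 3. Against 685 calls in the main fit, 408 probe sets were called over all rows (101 higher and 307 lower). Of these 408, 294 were shared with the 685, and some were probe sets outside the named genes. The calls numbered 2865 with array weights (1348 and 1517), 261 at adjusted p under 0.01 (64 and 197), and 272 to 1565 with 1 array left out (63 to 739 higher, 199 to 826 lower). The highest of these was without siChe-1 replicate 1, which shared 684 calls with the full set, and array weights gave that array 0.22. With the replicate block, 1145 genes were called (416 higher and 729 lower), 682 of them shared. Whether the numbers pair the arrays is not settled by the values. Same-numbered arrays deviated together with correlations of 0.23 (the highest of any pair across the groups), 0.064 and -0.045. Of the 6 arrays, 2 correlated best with their own number, and 3 arrays per group are too few to exclude pairing. The block made the anti-apoptotic list pass camera (-0.29, adjusted p = 0.0375), but not with an estimated correlation (adjusted p = 0.384). It made the ribosomal proteins fail (0.11, adjusted p = 0.0697), and the interferon list then had adjusted p = 0.124 with an estimated correlation. In the 10 splits of the 6 arrays, the labelled one called 685 genes and 13 lists, and it was the 1 split with as many of each. The highest of the others called 0 genes by limma (190 to 1277 at an unadjusted p under 0.05, against 3251) and 11 lists. The splits are too few for a share under 0.05. Each of the others also mixes arrays of both labelled groups. The labelled difference then widens the spread within its groups and partly stays between them. These splits therefore do not show what groups without a difference would give.

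The interferon list kept its direction in all of the alternatives (-3.71 to -2.93), and its camera call at the preset correlation, but not with an estimated correlation and the replicate block together, as above. The cause of the following changes was not tested. With another quantile normalization the mitotic (0.11) and cholesterol (0.14) lists passed camera, but not with an estimated correlation (adjusted p = 0.478 and 0.141). In that setting the respiratory chain (0.064) and Wnt (0.0013) medians turned, and the replication median was -0.086. After centring, the mitotic (-0.012) and autophagy (-0.035) medians turned and the ribosomal proteins (0.073) no longer passed. Averaging probe sets turned the respiratory chain (0.020). Array weights made the mitotic (0.16) and cholesterol (0.12) lists pass camera, but not with an estimated correlation (adjusted p = 0.430 and 0.249). They ended the checkpoint (-0.085) and ribosomal protein (0.094) calls, and turned the autophagy (-0.017), respiratory chain (0.011) and housekeeping (0.0066) medians. With an estimated correlation 12 calls were lost, for medians of -0.16 (replication), -0.24 (checkpoint), -0.44 (assembly factors), 0.11 (ribosomal proteins), -0.16 (snoRNAs), 0.13 (histones), -0.15 (pro-apoptotic), 0.38 (ATF4), 0.15 (HIF), -0.65 (NF-kB), -0.41 (ERK) and -0.22 (YAP/TAZ). Fry lost the checkpoint (-0.24) and ribosomal protein (0.11) calls and passed housekeeping (-0.17). Over all alternatives the medians ranged from -1.17 to -0.56 for NF-kB, -0.36 to -0.20 for YAP/TAZ and -0.23 to -0.12 for pro-apoptotic genes. With 1 array left out the medians ranged from -0.32 to -0.095 for checkpoint, -0.053 to 0.067 for Wnt, -0.019 to 0.029 for autophagy, 0.060 to 0.15 for ribosomal proteins, -0.058 to 0.052 for fibroblast, -0.21 to -0.013 for housekeeping, -0.12 to 0.039 for intestinal, -0.00063 to 0.099 for leukocyte, -0.033 to 0.17 for mitotic, -0.024 to 0.029 for respiratory chain and -0.18 to -0.091 for p53 genes. Of the 80 named genes other than AATF, 0 changed sign in any alternative, but calls were lost: 23 over all rows, 6 with another quantile normalization, 1 after centring (H4C4), 2 with the intensity trend and robust prior (POLA2 and BAK1), 25, 19 and 25 without control replicate 1, 2 or 3, 10 without siChe-1 replicate 2 and 14 without siChe-1 replicate 3. The background correction could not be varied without scanner files. Without detection calls, differences of genes near the floor are the least certain.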

Other observations

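The gene groups and the FOXO test here were chosen after the result was seen, so the counts of the first groups describe genes picked for their pattern and are not independent evidence of it. Of 12 measured genes of antigen presentation and the immunoproteasome, 9 were lower in the arrays labelled siChe-1 and none was higher by limma (median -1.28 on the log2 scale). PSMB9, an immunoproteasome subunit, was 7.74-fold lower (5.68 ± 0.15 against 8.63 ± 0.27, SD, n = 3 each). ERAP1, which trims peptides, was 4.40-fold lower, TAP1 3.44-fold and TAP2 3.15-fold lower. PSMB9 and TAP1 are also in the interferon list.

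Of 21 interferon, receptor and RNA sensor genes, 10 were lower and none was higher by limma (median -0.28). The type III interferons IFNL2 (6.09-fold), IFNL1 (3.73-fold) and IFNL3 (2.30-fold) were lower. IFNL2 and IFNL3 have near-identical sequences, so the split between IFNL2 and IFNL3 is uncertain. IFNB1 read 2.61 ± 0.21 in the arrays labelled control and 2.33 ± 0.12 in those labelled siChe-1 (SD, n = 3 each, limma adjusted p = 0.340). Both levels are near the low end of the scale and not shown to be above background, so they do not show that IFNB1 was unchanged. The double-stranded RNA sensors TLR3 (3.55-fold) and EIF2AK2 (2.93-fold) were lower. Of the receptors, IFNGR2 was lower (1.72-fold, limma adjusted p = 0.0295), and IFNAR1 (-0.19, adjusted p = 0.629) and IFNAR2 (0.014, adjusted p = 0.970) did not pass.

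SESN3, CCNG2 (2.32-fold) and TSC22D3 (2.16-fold), known FOXO targets, were higher in the arrays labelled siChe-1. The hypothesis that FOXO-responsive genes may rise as a group was tested on 21 others. It was not borne out: the median was 0.095, 1 gene was higher (BCL6) and 1 lower (GADD45A), and camera in limma gave adjusted p = 0.448 over the 3 added lists. Some members were dim, such as TXNIP (3.14 in the arrays labelled control and 3.06 in those labelled siChe-1) and PIK3IP1 (3.46 and 3.85). These levels are not shown to be above background, so a small rise of such genes could have been missed.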
